A study of Mus musculus with 6 samples.

How the data were processed

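Gene expression was measured on 6 Affymetrix mouse arrays, each hybridised with labelled RNA from Ba/F3 cells. Ba/F3 is a mouse pro-B cell line that needs interleukin 3 (IL3) to grow unless an active kinase replaces it. Per the labels' protocols, the cells carried ETV6-PDGFRB, FIP1L1-PDGFRA or an empty retroviral vector. Cells with a fusion gene were selected for growth without IL3, and the vector cells were kept in IL3. Each line was left untreated or given 100 nM imatinib (Glivec), an inhibitor of the PDGF receptor, ABL and KIT kinases, for 4 h. The medium held 10% serum, and 5 µg of RNA went into each labelling reaction. There was 1 array per line and treatment, so no difference within a line has a replicate check, and the number of arrays limits the precision of every value.

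The deposited values were intensity signals on a linear scale, 1 per probe set and array, made by the authors with GCOS 1.4.0 and MAS5, per the submitters' processing notes. Detection calls and background settings were not given in the sources used here. The values showed that each array had been scaled to a common level, since the mean signal after trimming 2% at each end was 100.0 on every array. Per array, 49.8% to 50.6% of the 22690 probe sets lay above the signal floor described next. The floor is set from the 50th percentile of the arrays, so these shares are near 50% by construction and do not measure detection. The ratio of 3' to 5' probe sets was 1.12 to 1.22 for actin and 0.754 to 0.802 for Gapdh.

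Probe sets were named through the platform annotation, in which 20393 had 1 gene symbol, 691 had several and 1606 had none. These counts include 64 control probe sets, which were not used for any gene. No symbol changed when looked up by gene number in the RefSeq gene table of the GRCm38.p6 assembly. Each of the 12393 genes was represented by its probe set with the highest mean log2 signal over the 6 arrays. The signal floor was the median over arrays of the 50th percentile, 20.1, and lower signals were set to it. Of the genes, 7018 exceeded the floor on at least 1 array. A log2 ratio of 2 arrays was computed where at least 1 of them exceeded the floor, and where only 1 did, the fold is a lower bound and is written as at least that size. The files name no genome build, and positions were not used here.

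Within a line, and between untreated lines, genes were counted past a 2-fold limit with no test. A gene counted as shared when it passed 2-fold in the same direction in both fusion lines and stayed under 2-fold in the IL3 pair. The 2 fusion lines were also treated as repeats of a PDGFR fusion line in limma 3.58.1 (R 4.3.3). The model had the line as a block and 1 coefficient for imatinib in fusion cells, with moderated variances (eBayes) and Benjamini-Hochberg adjustment over the 6808 genes above the floor on at least 2 arrays. The difference of the IL3 pair counted as spread, leaving 2 residual degrees of freedom and 3.10 prior ones. The p-values therefore measure spread between lines and within the IL3 pair, not between repeat cultures. Values set to the floor add no spread, so the SE and p are too small for genes with such arrays, among them Iigp1 and Gbp2b, which were below it on both IL3 arrays. Where a fusion array was below the floor, the log2 change is given without SE. It is a lower bound only for genes that moved the same way in both lines and had a signal above the floor in each. Adjusted p under 0.05 is the threshold for the words rose and fell, and the log2 changes given with an SE come from this fit. Simulated data with 200 changed genes among 6808 gave 96% recovery at a log2 change of 1 and 100% at 2. Of the simulated calls 1.51% were false, and there were 0 calls when nothing changed. The simulated noise was that of the IL3 pair, so it held no difference in drug response between the fusion lines. These rates therefore describe the simulated data only and cannot show how many of the calls on the real arrays are false.

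Before the data were examined, 24 gene lists were fixed: interferon-stimulated genes, STAT5 targets, ERK feedback and immediate early genes, MYC targets and ribosome biogenesis, ATF4 and amino acid genes, glycolysis, NF-kappaB targets, heat shock and ER chaperones, sterol and fatty acid synthesis, FOXO targets, E2F and G1/S genes, G2/M genes, cell cycle inhibitors and G1 cyclins, p53 targets, the BCL2 family, cytokine receptors and JAK-STAT genes, housekeeping genes, homologs of the fusion partners, and markers of B, mast, myeloid, T and NK, erythroid and fibroblast cells. Some genes stand in more than 1 list. Of 757 entries, 673 matched a gene, and members without a singly annotated probe set were not analysed here. A list's median log2 ratio was placed among 10000 random lists of the same size matched on mean signal in 20 bins (Python 3.11.15, numpy 2.4.6, pandas 2.3.3). That percentile describes these arrays only. Of 22 lists on simulated ratios without change, 0 fell outside the central range of random lists, and a list shifted by 0.5 came out at percentile 100. The simulated ratios were those of the IL3 pair assigned to genes at random, so list members did not move together. This check therefore cannot show how often real lists leave that range.

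Genes named in the text follow a rule set at the same time. It took the 12 shared genes that were highest and the 12 lowest by the smaller of their 2 absolute ratios, 4 genes each way in the IL3 pair and, among genes above the floor on all 4 fusion arrays, for the difference between fusion lines, 10 genes each way for untreated fusion lines, up to 4 members of each list by absolute mean ratio, and a set of known STAT5, ERK, MYC, apoptosis and receptor genes. Genes outside it are said to have been chosen after their values were seen. Both untreated comparisons share the IL3 array, so chance values were simulated 100 times with unchanged lines against that array. The simulated noise was that of the IL3 pair, so it held no differences between separately selected lines. The treated IL3 array was used as a separate reference. Alternatives were floors at the 40th and 60th percentiles, a pseudocount of 16 with no floor, quantile normalization, median centring, a loess of ratio on signal (span 0.4, statsmodels 0.14.6), the mean of all probe sets per gene, leaving out probe sets marked as shared between transcripts, limits of 1.5-fold and 3-fold, and other limma fits. Scaling to 18 spiked hybridization control probe sets was added after seeing the data.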

Results

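The expression arrays covered 3 Ba/F3 lines, each with 1 untreated and 1 imatinib array. The fusion genes ETV6-PDGFRB and FIP1L1-PDGFRA come from myeloid neoplasms with eosinophilia and encode constantly active receptor kinases. The design asks which transcripts depend on these kinases, with IL3-grown vector cells as the control for the drug itself. Across 7018 genes, log2 signals of the IL3 pair correlated at r = 0.994, against 0.956 for the ETV6-PDGFRB pair and 0.957 for the FIP1L1-PDGFRA pair. The untreated fusion arrays correlated with each other at 0.979 and the treated ones at 0.980.

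Imatinib lowered interferon-stimulated genes, cytokine signalling targets, MYC and genes of ribosome production in ETV6-PDGFRB cells after 4 h, and E2F, G2/M and FOXO target genes were higher. The signal of Iigp1, an interferon-induced GTPase of the immunity-related family, went from 1476 to 45.9, a 32.2-fold lower level. Socs1, a STAT-induced inhibitor of JAK kinases, went from 213 to below the floor, at least 10.6-fold lower. Cish, a STAT5 target, was 5.03-fold lower, and Myc was 2.83-fold lower, at 656 before and 232 after. Ccng2, a cyclin with high levels in resting cells, was 4.42-fold higher, at 108 before and 477 after. Of 6852 measured genes, 110 were at least 2-fold higher and 196 at least 2-fold lower. The SD of all log2 ratios was 0.50, against 0.20 in the IL3 pair. For imatinib in ETV6-PDGFRB cells, scaling to the hybridization controls, chosen after seeing the data, gave 50 higher and 311 lower genes.

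The same groups were lower in FIP1L1-PDGFRA cells. Iigp1 went from 617 to 36.7, a 16.8-fold lower level, and Socs1 from 207 to below the floor, at least 10.3-fold lower. Cish was 8.87-fold lower, at 552 before and 62.2 after, and Myc was 3.79-fold lower. Klf1, a transcription factor of red cell development, was 5.82-fold higher in this line and 3.02-fold higher in ETV6-PDGFRB cells. Of 6743 measured genes, 148 were at least 2-fold higher and 200 at least 2-fold lower, with an SD of log2 ratios of 0.51. For imatinib in FIP1L1-PDGFRA cells, scaling to the hybridization controls gave 58 higher and 392 lower genes.

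In IL3-grown vector cells, Myc, Cish, Socs1 and Ccng2 stayed near their untreated levels with imatinib, while Iigp1 was below the floor on both arrays and has no ratio. Myc was 724 before and 722 after, Cish 309 and 297, Socs1 85.0 and 76.7, and Ccng2 55.5 and 55.6. Of 6674 measured genes, 5 were at least 2-fold higher and 4 lower. The highest log2 ratios were those of Mpnd (at least 1.68), Nfic (1.61), Rps27 (1.19) and Dennd10 (1.07). The lower genes were Sbf2 (-1.30), Cysrt1 (at least 1.26 lower), Mad1l1 (-1.06) and Pink1 (-1.01), all with signals under 50 on the untreated array. A floor at the 40th percentile raised the count from 9 to 49 genes, and one at the 60th percentile lowered it to 2.

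Both fusion lines shared 50 genes that were higher and 126 that were lower past 2-fold. The rule leaves out genes past 2-fold in the IL3 pair, and the counts were the same without that part. Some of the genes, such as Iigp1 and Gbp2b, were below the floor in IL3 cells and have no ratio there. Independent lists of the same sizes would share 2.43 higher and 5.73 lower genes among 6640. The shared lower genes were led by interferon-induced genes, namely Iigp1, Ifit1, Gbp2b, Rtp4, Usp18, Irgm2, Irgm1, Igtp and Ifi47, together with Socs1, the protease-activated receptor gene F2rl2 and Metrnl, which encodes a secreted protein. F2rl2 was 270 before and 40.2 after in ETV6-PDGFRB cells and 527 and 81.9 in FIP1L1-PDGFRA cells. The shared higher genes were led by Ccng2, Tnfaip2, Hemgn, Mettl7a1, Plxdc1, Col5a1, Klf1, Ampd3, Mxd4, Bbip1, Mettl7a2 and Trp53inp1. Hemgn and Klf1 are erythroid genes, Mxd4 encodes a protein that competes with MYC for its partner MAX, and Col5a1, a collagen gene, went from 438 to 1324 and from 252 to 1173. Scaling to the hybridization controls gave 18 higher and 205 lower genes for imatinib shared by both fusion lines, 2-fold rule.

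**Figure D1:**
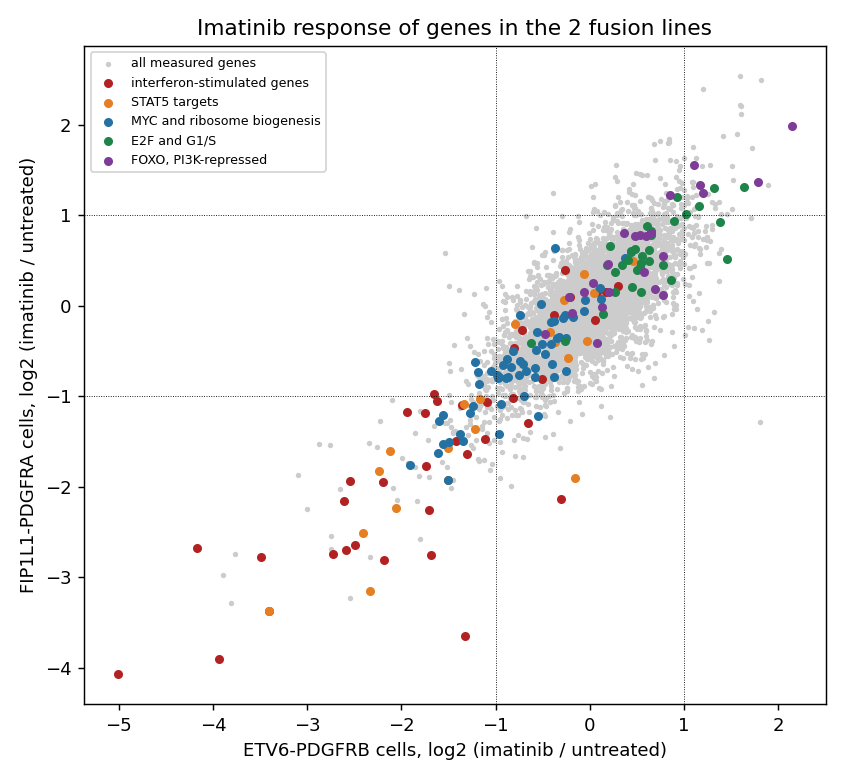
Each point is a gene, with the log2 ratio of imatinib over untreated signal in ETV6-PDGFRB cells on the x axis and in FIP1L1-PDGFRA cells on the y axis, 1 array per group. Colours mark 5 gene lists, dotted lines mark 2-fold, and 126 genes lie past 2-fold in the lower left corner against 50 in the upper right.

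Across 6497 genes, the responses of the fusion lines correlated at r = 0.752 (Spearman 0.699). Genes are not independent replicates, and no p-value is attached. The correlations with the IL3 pair were 0.018 for ETV6-PDGFRB and 0.050 for FIP1L1-PDGFRA. Of 302 genes past 2-fold in ETV6-PDGFRB cells and measured in both lines, 287 had the same sign in FIP1L1-PDGFRA cells, and of 345 past 2-fold in FIP1L1-PDGFRA cells, 341 had the same sign in ETV6-PDGFRB cells. With a floor at the 40th percentile r was 0.689, and with the pseudocount it was 0.624.

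In the limma fit across both fusion lines, 916 genes rose and 841 fell with imatinib, out of 6808. Iigp1 fell by 4.54 ± 0.22 on the log2 scale (SE, adjusted p = 0.00191), Ifit1 fell as well (-3.92 or lower, adjusted p = 4.53e-04), as did Socs1 (-3.39 or lower, adjusted p = 7.97e-04), and Gbp2b fell by 3.55 ± 0.14 (adjusted p = 0.00135). Ccng2 rose by 2.07 ± 0.09 (adjusted p = 0.00156), Tnfaip2 by 2.16 ± 0.24 (adjusted p = 0.00749) and Klf1 by 2.07 ± 0.23 (adjusted p = 0.00749). With the 4 fusion arrays alone, limma gave 418 genes that rose and 471 that fell. Of the 104 named genes tested, 16 lost their limma call in that fit, among them Btk, Epor, Hspa5, Gata2, Adgre1, Idi1, Etv6 and Socs2. With hybridization control scaling 395 genes rose and 1880 fell. A test of the difference between the fusion response and the IL3 pair gave 0 genes by limma, with 1179 at an unadjusted p under 0.05 and a lowest adjusted p of 0.114, so the contrast with IL3 cells rests on the values of single arrays.

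Interferon-stimulated genes fell as a group. Of 38 tested, 30 fell, 0 rose and 8 did not pass, and adjusted over the list alone 31 fell and 1 rose. The median log2 ratio was -1.52 in ETV6-PDGFRB and -1.48 in FIP1L1-PDGFRA cells, below all 10000 random lists. In the IL3 pair it was -0.02, over only the 24 members with a signal above the floor there, since members below it have no ratio. Igtp, a GTPase of the family of Iigp1, went from 2015 to 112 and from 861 to 135.

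STAT5 targets, which cytokine receptors switch on, fell in 12 of 23 cases, with 1 rising and 10 not passing. Adjusted over the list alone, 15 fell and 1 rose. Median log2 ratios were -1.01 and -1.12, below all random lists, and -0.62 and -1.01 with the pseudocount. Cish fell by 2.74 ± 0.20 (limma adjusted p = 0.00383), and Id1, an inhibitor of differentiation, fell by 2.46 ± 0.09 (adjusted p = 8.07e-04). The interleukin 4 receptor gene Il4ra fell by 2.14 ± 0.13 (adjusted p = 0.00274). The survival kinase gene Pim1 fell by 2.03 ± 0.13 (adjusted p = 0.00311), and Socs2 by 0.39 ± 0.08 (adjusted p = 0.0304).

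ERK feedback and immediate early genes included 15 that fell, 0 that rose and 8 that did not pass among 23, and 18 fell adjusted over the list alone. Their medians were -0.81 and -0.99, and -0.38 and -0.59 with the pseudocount. Dusp6, an ERK phosphatase induced by ERK, fell by 1.93 ± 0.20 (limma adjusted p = 0.00695), going from 374 to 73.9 and from 278 to 97.0. Ier2 fell by 1.42 ± 0.16 (adjusted p = 0.00767) and Nab2 fell as well (-1.39 or lower, adjusted p = 0.0132). Egr1 and Spry4 were below the floor on every array.

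MYC targets and ribosome biogenesis genes fell in 43 of 58 cases, with 1 rising and 14 not passing. Adjusted over the list alone, 47 fell and 1 rose. The medians were -0.72 and -0.68, and 0.00 in the IL3 pair. Myc itself fell by 1.71 ± 0.12 (limma adjusted p = 0.00383), the nucleolar gene Rrp1b by 1.83 ± 0.09 (adjusted p = 0.00199), the spermidine synthase gene Srm by 1.62 ± 0.09 (adjusted p = 0.00269) and the ribosome assembly gene Wdr43 by 1.54 ± 0.09 (adjusted p = 0.00274).

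In the ATF4 and amino acid list 16 of 34 fell, 2 rose and 16 did not pass, with 19 falling and 2 rising adjusted over the list alone. Atf4 fell by 1.10 ± 0.19 (limma adjusted p = 0.0177) and Tars, a threonine tRNA ligase gene, by 0.98 ± 0.13 (adjusted p = 0.0093). In the glycolysis list 7 of 19 fell and 1 rose, and the counts were the same adjusted over the list alone. The hexokinase gene Hk2 fell by 1.25 ± 0.10 (adjusted p = 0.00399) and the glucose transporter genes Slc2a3 by 1.22 ± 0.08 (adjusted p = 0.00355) and Slc2a1 by 0.87 ± 0.13 (adjusted p = 0.0123). Among 21 NF-kappaB targets 7 fell and 3 rose, or 8 and 3 adjusted over the list alone. The members that fell included Cxcl10, Irf1 and Il6, and Tnfaip2 rose. Heat shock and ER chaperone genes fell in 6 of 26 cases, but in 1 adjusted over the list alone. The ER chaperone gene Hspa5 fell by 0.62 ± 0.16 (adjusted p = 0.0433). Sterol and fatty acid synthesis genes rose in 4 and fell in 3 of 28 cases, or 6 and 6 adjusted over the list alone. Idi1, of the sterol pathway, fell by 0.86 ± 0.17 (adjusted p = 0.0235).

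FOXO targets and genes repressed by PI3K signalling rose in 13 of 24 cases, with 1 falling and 10 not passing. Adjusted over the list alone, 15 rose and 1 fell. The medians were 0.55 and 0.50, above all random lists, and 0.09 (percentile 97.8) in the IL3 pair. With the pseudocount the fusion line medians were 0.15 (percentile 99.2) and 0.20, with hybridization control scaling 0.37 and 0.23, and with the mean of all probe sets 0.45 and 0.27. Besides Ccng2, Trp53inp1 rose by 1.58 ± 0.13 (limma adjusted p = 0.00421), the growth arrest gene Gadd45a by 1.33 ± 0.17 (adjusted p = 0.00956) and the autophagy kinase gene Ulk1 by at least 1.25 (adjusted p = 0.00467). Bcl2l11, which encodes the death protein BIM and is a FOXO target, was 338 before and 325 after in ETV6-PDGFRB cells and 301 and 336 in FIP1L1-PDGFRA cells (log2 change 0.05 ± 0.10, limma adjusted p = 0.731).

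Genes of DNA replication and mitosis rose. Of 34 E2F and G1/S genes, 25 rose, 1 fell and 8 did not pass, with 29 and 2 adjusted over the list alone. Of 35 G2/M genes, 20 rose, 0 fell and 15 did not pass, with 24 rising adjusted over the list alone. The E2F medians were 0.54 and 0.51, and the G2/M medians 0.42 and 0.44, all above the 10000 random lists. In the IL3 pair the medians were 0.06 (percentile 98.9) and 0.04 (percentile 92.4). With hybridization control scaling the E2F medians were 0.36 and 0.23 and the G2/M medians 0.24 and 0.17. The repressor gene E2f8 rose by 1.48 ± 0.11 (limma adjusted p = 0.00383), E2f1 by 1.31 ± 0.22 (adjusted p = 0.0165) and the replication licensing gene Cdc6 by 1.13 ± 0.13 (adjusted p = 0.00807). Cdca3 rose by 0.72 ± 0.08 (adjusted p = 0.00805) and Nusap1, of the mitotic spindle, by 0.71 ± 0.09 (adjusted p = 0.00873).

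Cell cycle inhibitors and G1 cyclins moved both ways, with 8 of 19 rising and 3 falling over all genes and adjusted over the list alone. Cdkn1b, which encodes the inhibitor p27, rose by 1.23 ± 0.21 (limma adjusted p = 0.018). Cdkn1a, which encodes p21, fell by 1.10 ± 0.09 (adjusted p = 0.00449), and the cyclin gene Ccnd2 fell by 1.21 ± 0.11 (adjusted p = 0.00542). Among 18 p53 targets 6 rose and 3 fell, on both adjustments, and Ddb2, a DNA repair gene, rose by 1.08 ± 0.17 (adjusted p = 0.0152). In the BCL2 family 2 of 10 rose and 0 fell, on both adjustments. These were the death genes Bbc3 (0.92 ± 0.09, adjusted p = 0.00608) and Bad (0.57 ± 0.10, adjusted p = 0.0164). The survival gene Bcl2l1 did not pass (-0.50 ± 0.15, adjusted p = 0.0713). Bcl6 was below the floor on every array.

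**Figure D2:**
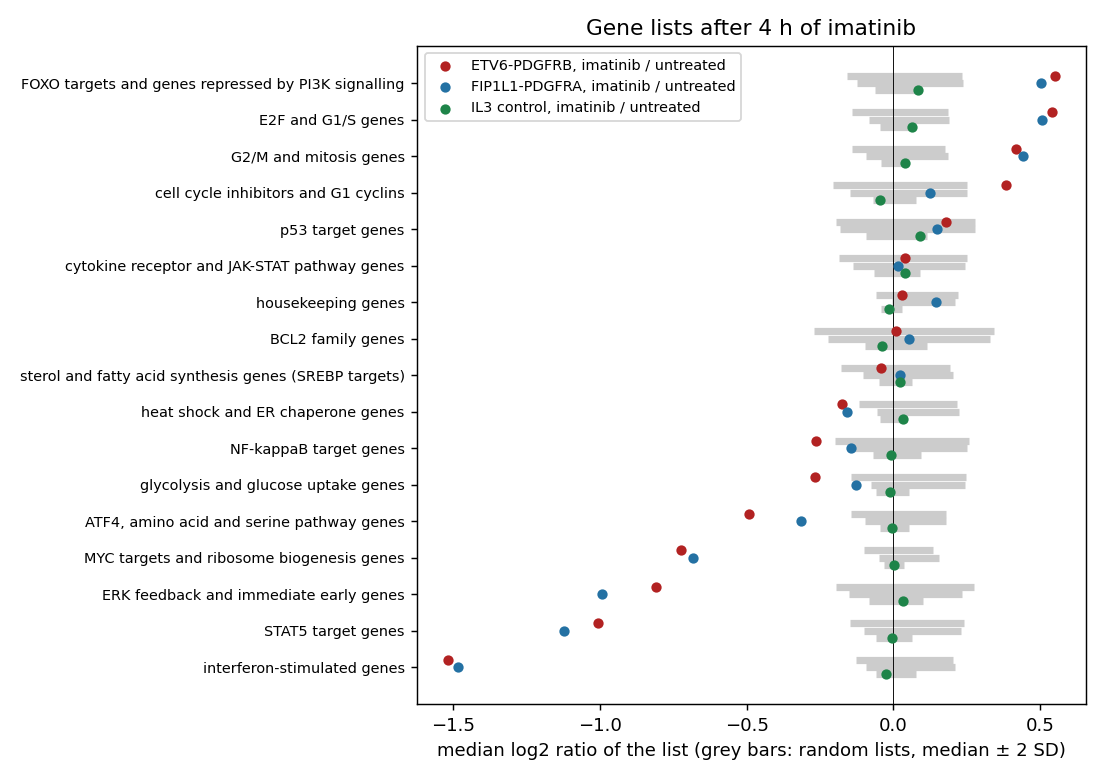
Points give the median log2 ratio of imatinib over untreated signal (x axis) for the gene lists with at least 10 measured members (y axis), coloured by cell line, and grey bars give the median ± 2 SD of matched random lists. Interferon-stimulated genes are lowest at -1.52 and -1.48 in the fusion lines, and the FOXO and E2F lists are highest.

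Among cytokine receptor and JAK-STAT genes 4 of 22 rose and 3 fell, on both adjustments. Spred1, an ERK pathway inhibitor, fell by 1.25 ± 0.11 (limma adjusted p = 0.00478), and the erythropoietin receptor gene Epor rose by 0.85 ± 0.21 (adjusted p = 0.0421). The IL3 receptor gene Il3ra did not pass (0.42 ± 0.14, adjusted p = 0.0781). Of 27 housekeeping genes 0 rose and 1 fell, and 0 passed adjusted over the list alone. Their medians were 0.03 and 0.14, and -0.15 and -0.13 with hybridization control scaling.

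Lineage markers were mostly below the floor. Erythroid markers rose in 3 of 7 cases and fell in 1, and mast cell, basophil and eosinophil markers rose in 4 of 9 and fell in 1, on both adjustments. Gata1, shared by both lineages, rose by 0.91 ± 0.14 (limma adjusted p = 0.0141), Gata2 by 0.66 ± 0.17 (adjusted p = 0.0445), and the transferrin receptor gene Tfrc fell by 0.76 ± 0.08 (adjusted p = 0.00754). Among 8 B cell markers 1 rose, Cd79b, and 1 fell, Btk. The macrophage marker Adgre1 fell among 6 myeloid markers, and Acta2 among 3 fibroblast markers (-0.57, but 0.57 with the mean of all probe sets). Of 3 T and NK cell markers 0 passed, and Zap70 among them moved in opposite directions in the fusion lines. These counts held adjusted over each list alone.

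The fusion partners were read through the mouse homologs, and whether their probe sets detect the human fusion transcripts is not known. Pdgfra and Pdgfrb were below the floor on all 6 arrays. Of the 2 tested, Etv6 fell by 0.68 ± 0.16 (limma adjusted p = 0.0367), with signals of 23.8 to 58.5, and Fip1l1 ranged from 117 to 143 and did not pass (adjusted p = 0.757). The count was 1 adjusted over the list alone. These values check no label.

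The response differed between the fusion lines by more than 2-fold for 94 genes, of which 46 had the higher ratio in ETV6-PDGFRB and 48 in FIP1L1-PDGFRA cells. The largest difference was that of Zap70, a T cell kinase gene, at least 3.08 on the log2 scale, with signals of 25.1 and 87.8 in ETV6-PDGFRB cells and 48.7 and below the floor in FIP1L1-PDGFRA cells. Among genes above the floor on all 4 fusion arrays, the interferon-induced gene Ifit2 went from 104 to 84.2 in ETV6-PDGFRB cells and from 216 to 49.1 in FIP1L1-PDGFRA cells. Mrpl33, Ccdc93 and Clec2d had log2 ratios of 1.26, 0.68 and 1.20 in ETV6-PDGFRB cells and -0.38, -0.80 and -0.26 in FIP1L1-PDGFRA cells. On the other side, Tcl1b3 (-1.54 and 0.58), Sbf2 (-0.68 and 0.99) and Cerk (-0.39 and 1.25) had lower ratios in ETV6-PDGFRB cells, and Igtp was lower after imatinib in both lines (-4.17 and -2.68). The count was 232 with a floor at the 40th percentile and 42 at the 60th, and hybridization control scaling gave 65 and 27. With 1 array per group these differences were not tested.

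Without imatinib, interferon-stimulated genes were far higher in both fusion lines than in IL3-grown vector cells. The fusion lines were selected and grew without IL3, so the untreated comparisons cannot separate IL3 supply and selection from the fusion gene. Iigp1, at 11.3 in IL3 cells and so below the floor, was at least 73.5-fold higher in ETV6-PDGFRB and at least 30.7-fold higher in FIP1L1-PDGFRA cells. Gbp2b was at least 103-fold and at least 41.4-fold higher. Ifi47, at 23.2 in IL3 cells, reached 1303 and 771. The 10 genes with the highest ratios in both lines were Gbp2b, Ifi47, Gbp2, Iigp1, Rtp4, Oasl2, Gbp7, Igtp, Irgm2 and Ifit1.

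Against IL3 cells, 152 genes were at least 2-fold higher and 50 lower in ETV6-PDGFRB cells, and 122 higher and 22 lower in FIP1L1-PDGFRA cells. Both lines shared 87 higher and 6 lower genes, with 31 of the 87 in the interferon list. The 6 lower genes were Padi2, Wasl, Lat, Dok2, Slc14a1 and Ptgir. Wasl was 49.2 in IL3 cells and below the floor in both lines, and its mean log2 ratio was 0.34 when probe sets marked as shared were left out. The comparisons share the IL3 array. Unchanged lines simulated against it with the noise of the IL3 pair shared 6.13 genes on average and 11 at most. That noise leaves out differences between separately selected lines. Independent lists would share 2.60 higher and 0.165 lower genes. The ratios of the lines correlated at r = 0.706 across genes (simulated 0.526), with a covariance of 0.139 (simulated 0.0253). With the untreated IL3 array for one line and the treated one for the other, 84 higher and 6 lower genes were shared. With a floor at the 40th percentile, 315 genes passed 2-fold in ETV6-PDGFRB cells in place of 202.

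The interferon list had 32 of 38 members at least 2-fold higher in ETV6-PDGFRB and 34 of 38 in FIP1L1-PDGFRA cells, with medians of 2.08 and 2.44. NF-kappaB targets had medians of 0.41 and 0.24, the first above all random lists, with Cxcl10, Irf1 and Il6 farthest from 0, and 0.19 and 0.0931 with the pseudocount. Irf1, a transcription factor induced by interferon, was 57.7 in IL3 cells, 403 in ETV6-PDGFRB and 175 in FIP1L1-PDGFRA cells. STAT5 targets had medians of 0.06 (-0.05 with hybridization control scaling) and 0.34, and the log2 ratios of Socs1 were 1.32 and 1.29. E2F and G1/S genes were lower, with medians of -0.16 and -0.22, and -0.27 and -0.0688 with hybridization control scaling. Myc was 724 in IL3 cells, 656 in ETV6-PDGFRB and 681 in FIP1L1-PDGFRA cells. Bcl2l11 was 156 in IL3 cells, 338 in ETV6-PDGFRB and 301 in FIP1L1-PDGFRA cells. Mast cell genes differed between the lines. Cma1, a mast cell chymase gene, was 216 in IL3 cells, 2574 in ETV6-PDGFRB and 113 in FIP1L1-PDGFRA cells, and the protease gene Cpa3 was 166, 814 and 94.7. Acta2, a smooth muscle actin gene, was 41.4, 462 and 56.2.

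Genes that were higher in a fusion line could be followed on arrays that share nothing with that comparison. Of 147 genes at least 2-fold higher in untreated ETV6-PDGFRB cells, 54 (36.7%) were at least 2-fold lower after imatinib in FIP1L1-PDGFRA cells, against 3.01% of all genes. Of 119 genes higher in untreated FIP1L1-PDGFRA cells, 55 (46.2%) were lower after imatinib in ETV6-PDGFRB cells, against 2.94% of all genes. Genes lower in a fusion line gave few cases of the converse, with 2 of 50 (4%) at least 2-fold higher after imatinib in FIP1L1-PDGFRA cells, against 2.19% of all genes, and 1 of 22 (4.55%) in ETV6-PDGFRB cells, against 1.56%. After 4 h of imatinib the interferon list was still above treated IL3 cells, with medians of 1.16 and 1.06. MYC targets were below them, at -0.75 and -0.72.

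**Figure D3:**
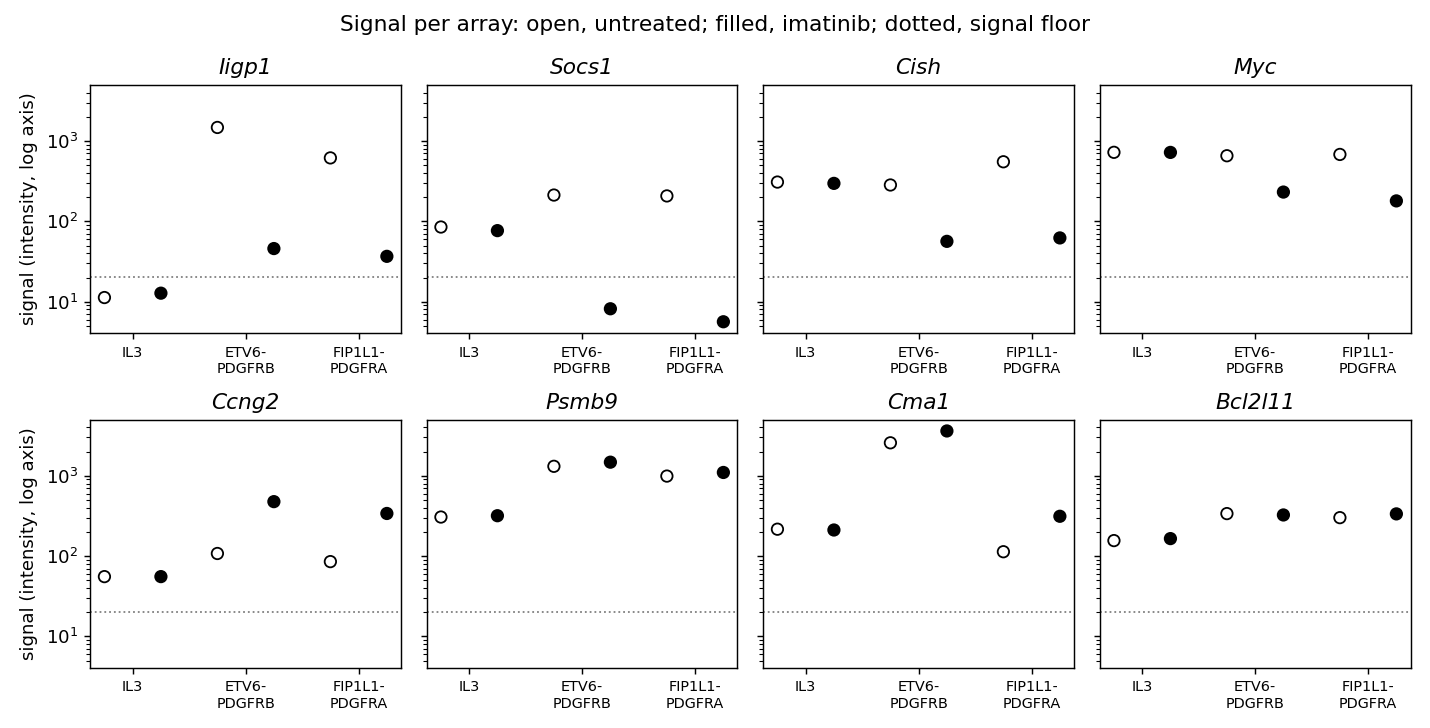
Signal intensity (y axis, log scale) of 8 genes on each of the 6 arrays, grouped by line on the x axis, with open points for untreated and filled points for imatinib arrays and a dotted line at the floor of 20.1. Iigp1 goes from 1476 to 45.9 and from 617 to 36.7 in the fusion lines, while Bcl2l11 stays between 301 and 338 in them.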

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

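The tests in this part were all chosen after the results were seen, and the details of 3 of them were changed after a first look at their values, which changed no verdict.

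Zap70, a T cell kinase gene, stood out through opposite responses past 2-fold in the fusion lines. Its signal went from 25.1 to 87.8 in ETV6-PDGFRB cells and from 48.7 to below the floor in FIP1L1-PDGFRA cells, a log2 difference of at least 3.08. The difference was not tested. Signal in data left out of the gene comparisons was the reason to look at probe sets without a single gene. Of 905 measured in both fusion lines, 23 passed 2-fold in the same direction in both, 18 lower and 5 higher. The spiked hybridization controls were looked at for the same reason. Their mean log2 signal was 0.184 higher after imatinib in ETV6-PDGFRB cells, 0.274 higher in FIP1L1-PDGFRA cells and 0.009 higher in IL3 cells. They enter with the hybridization mix, so these differences do not measure RNA per cell.

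Interferon-stimulated genes were higher in both fusion lines than in IL3 cells and lower after imatinib. Array scaling was looked at first, and the list median after imatinib nearest to 0 over the scalings was -1.468. The largest move of the median ratio of all genes under these scalings was -0.27, in FIP1L1-PDGFRA cells. The test could therefore not have come out near 0, and it shows only that none of these scalings removes the fall. Cross-hybridization within gene families would spare members outside the large families, whose median nearer to 0 was -1.325. The list stayed above treated IL3 cells, with medians of 1.16 and 1.06, and its 7 antigen presentation members, chosen after their values were seen, had imatinib medians of 0.06 and 0.15. Whether interferon, the fusion kinase itself or slow transcript decay sets these levels was not tested. In the comparison of untreated lines, lack of IL3 and selection cannot be told apart from the fusion gene.

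S phase and mitosis genes were higher after imatinib in both fusion lines. Scaling might raise all genes of an array. The lowest medians over the scalings were 0.234 for the E2F and G1/S list and 0.170 for the G2/M list. The largest move of the median ratio of all genes was -0.27, in FIP1L1-PDGFRA cells, where the list medians were 0.51 and 0.44 as deposited. A move of that size could not bring either list to 0. The test therefore shows only that none of these scalings removes the rise. An imatinib effect on any Ba/F3 cell would appear in the IL3 pair, where 28 of 34 E2F members lay above 0 but the median was 0.064 (percentile 98.9). A small shift in the same direction in IL3 cells is therefore left, and it was far below the fusion line medians of 0.54 and 0.51. It comes from 1 pair of arrays of cells grown with IL3. That pair cannot show an imatinib effect that appears only without IL3. The cell cycle phase of the cultures was not measured.

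Mast cell protease genes were higher in the ETV6-PDGFRB line. Mast cells mixed into the culture could bring other mast cell transcripts, but the highest signal of Kit, Ms4a2, Fcer1a, Tpsab1 and Tpsb2 in untreated ETV6-PDGFRB cells was 4.79, under the floor. Ba/F3 arrays offer no positive control for those probe sets, so the test is weak. A difference between clones or selections and an effect of the fusion gene cannot be told apart with 1 line per fusion gene.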

How the results depend on the processing

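The limma fit paired treated and untreated arrays by line. Apart from that pairing, no paired analysis was possible because the columns carry no replicate numbers and each line and treatment had 1 array. On each array, many probe sets lay under the floor, so low transcripts have no ratio and folds from them are lower bounds. Scaling to the hybridization controls moved the median log2 ratio by -0.18 in ETV6-PDGFRB and -0.27 in FIP1L1-PDGFRA cells and by -0.01 in the IL3 pair, and untreated comparisons by -0.11 and 0.15. Where a value moved below, the cause was not tested unless stated. The interferon, STAT5, ERK and MYC lists stayed negative with imatinib, and the E2F, G2/M and FOXO lists positive, under quantile normalization, the pseudocount, the mean of all probe sets and hybridization control scaling. Lists with too few members under a setting have no value there.

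The counts of genes past the limit moved as follows for imatinib in ETV6-PDGFRB cells, imatinib in FIP1L1-PDGFRA cells, imatinib in IL3 control cells, imatinib shared by both fusion lines, 2-fold rule, fusion lines against IL3 control cells, untreated: ETV6-PDGFRB, fusion lines against IL3 control cells, untreated: FIP1L1-PDGFRA, both of these, and the difference of the imatinib response between the 2 fusion lines. With a 1.5-fold limit, which admits more genes by construction, they were in this order 1224, 1215, 97, 655, 667, 435, 213 and 552. With a 3-fold limit they were 69, 82, 2, 48, 82, 70, 58 and 9. A floor at the 40th percentile gave 49 genes in IL3 cells, 315 in untreated ETV6-PDGFRB cells, 232 for the line difference and r = 0.689 for agreement of the 2 fusion lines. The 60th percentile gave 2 in IL3 cells and 42 for the line difference. The pseudocount gave 189 in ETV6-PDGFRB cells, 224 in FIP1L1-PDGFRA cells and r = 0.624. The mean of all probe sets gave 30 genes in IL3 cells, and leaving out shared probe sets gave 5.

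For imatinib shared by both fusion lines, limma gave 889 genes with the 4 fusion arrays alone and 0 when the difference from the IL3 pair was tested. For imatinib shared by both fusion lines, limma gave 1847 with quantile normalization, 1569 with no floor, 1214 and 1906 with the 40th and 60th percentile floors, 2290 with a trend, 1704 with robust moderation, 1468 with the mean of all probe sets and 2275 with hybridization control scaling. Of the genes called by limma, 1713 were tested with the mean of all probe sets, where 1308 kept their call and 22 reversed sign, and the 60th percentile floor reversed 1 of 1610. Of 104 named genes, 16 lost their call with the 4 fusion arrays alone and 13 with the 40th percentile floor. Among the named genes, Acta2 reversed to 0.57 with the mean of all probe sets, and the untreated ratio of Wasl reversed to 0.34 without shared probe sets.

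In the rest of this part, list medians are taken over each gene's mean log2 ratio of both fusion lines. They are not the medians per line given in the Results. Hybridization control scaling moved imatinib medians to -0.60 for ATF4, -0.29 for the BCL2 family, -0.15 for B cells, -0.29 for cytokine receptors, 0.31 for E2F, 0.18 for erythroid, 0.30 for FOXO, 0.12 for inhibitors and G1 cyclins, 0.18 for G2/M, -0.41 for glycolysis, -0.39 for heat shock, -0.15 for housekeeping, -1.69 for interferon, -0.92 for MYC, 0.37 for mast cells, -0.33 for myeloid, -0.52 for NF-kappaB, -1.33 for STAT5, -0.27 for sterol and -0.0099 for p53 genes.

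The pseudocount, which shrinks low signals by construction, moved imatinib medians to -0.42 for ERK, 0.0616 for erythroid, 0.15 for FOXO, 0.0945 for inhibitors and G1 cyclins, -1.19 for interferon, 0.13 for mast cells, -0.19 for NF-kappaB, -0.53 for STAT5 and 0.11 for p53 genes. Untreated medians became -0.0058 for the BCL2 family, 0.0208 for cytokine receptors, 1.997 for interferon, -0.13 for myeloid, 0.12 for NF-kappaB and 0.0052 for p53 genes.

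The mean of all probe sets moved imatinib medians to 0.29 for B cells, 0.34 for FOXO, 0.16 for inhibitors and G1 cyclins, -0.24 for heat shock, 0.16 for housekeeping, -1.34 for interferon and -0.13 for NF-kappaB. Untreated medians became -0.24 for the BCL2 family, -0.0868 for FOXO, 0.27 for STAT5 and 0.24 for sterol genes. Quantile normalization moved housekeeping medians to 0.0032 with imatinib and 0.0022 without.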

Other observations

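Antigen presentation genes, chosen after their values were seen, were higher in the untreated fusion lines and stayed so with imatinib. Psmb8, Psmb9, Tap1, Tap2, H2-K1, H2-D1 and B2m had median log2 ratios to IL3 cells of 1.39 in ETV6-PDGFRB and 1.03 in FIP1L1-PDGFRA cells, with 4 of 7 at least 2-fold higher in each line. Their imatinib medians were 0.06 and 0.15, with 0 of 7 past 2-fold. Psmb9, a subunit of the immunoproteasome, was 307 in IL3 cells, 1312 before and 1477 after imatinib in ETV6-PDGFRB cells, and 992 and 1100 in FIP1L1-PDGFRA cells.

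The glycolysis and glucose uptake list was lower in untreated ETV6-PDGFRB cells than in IL3 cells, with 17 of 19 members below 0, 2 of them past 2-fold, and a median of -0.45, below all 10000 random lists, against -0.10 in FIP1L1-PDGFRA cells. Pdk1 and Bnip3 had log2 ratios of -1.62 and -1.40 in ETV6-PDGFRB cells and -0.22 and 0.30 in FIP1L1-PDGFRA cells. The mast cell protease genes Mcpt4 and Mcpt8, chosen after their values were seen, were 33.2 and 60.7 in untreated ETV6-PDGFRB cells, 54.9 and 79.8 after imatinib, and under the floor in the other lines. Adgre1 was 284 in IL3 cells, 61.4 in ETV6-PDGFRB and 270 in FIP1L1-PDGFRA cells.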
